A study of Drosophila melanogaster with 2 samples.

How the data were processed

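Chromatin immunoprecipitation with an anti-GFP antibody and sequencing were done on whole embryos of mixed sex, 0 to 24 h old, that carried a Mad-eGFP fusion, in 2 biological replicates. Chromatin was sheared by sonication to a size range of 200 to 800 bp, per the labels. Both samples formed 1 group, since the labels give no other condition, and each came from its own embryo collection record per the labels.

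The deposited peak lists give, for each of the builds dm6 and dm3, a list of 30000 peaks per replicate, a list of 30000 peaks called on both replicates together, and a list kept by a threshold on the irreproducible discovery rate, per the text files deposited with the samples. The same deposited texts record that each list was derived from the alignments of the replicates and of a control. The control data were not used here. The aligner, the peak caller, their versions and the read depths are not given in the sources used here. The signal of a peak is the value the authors' caller wrote, whose formula is not given in the sources used here, and it was used only to describe, rank and filter peaks within a list and to compare the replicates' ranks. The lists also hold a deposited −log10 q value per peak, in which 2544 of the 3590 thresholded peaks shared the highest value of 3.71, so it was not used to rank. Peak starts and ends and summit positions come from the deposited lists and are given counting from 1.

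All work on genes and sequence used build dm6 with Ensembl release 115 annotation, without transposable elements, and the release 6 genome sequence, on arms 2L, 2R, 3L, 3R, 4 and X. The dm3 lists were used only for peak counts and the comparison of the replicates. Summits were put into 7 classes in order of priority, with promoter (within 500 bp of any annotated TSS) first, then 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic. Shares have Wilson intervals at a confidence level of 95%. They cover counting error over peaks, and tests over peaks or genes describe these pooled lists and not the spread between embryos.

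A protein-coding gene was bound when a thresholded summit lay in its span extended by 5 kb on each side, so a summit at a neighbour's promoter counts too. The bound members of 21 gene lists, fixed before the data were examined, were compared with 100000 random lists matched on deciles of gene span length, with doubled one-sided p-values. In these lists 10 symbols were updated to the annotation's names, and the symbols dtg, ladybird, wrinkled and mir-1 were left out because no protein-coding gene of the annotation has them. The list medians of signal ranks were tested with 10000 random lists of bound genes. Each of 16 motifs was sought on both strands within 100 bp of the summit (201 bp) and in flanks of the same width centred 600 bp to each side. The flank share is the mean of both flanks and the exact McNemar test was made against the right one. Benjamini-Hochberg adjustment was over the classes, lists or motifs, with a threshold of 0.05. Replicate lists were compared by overlap of at least 1 bp, with the highest overlapping signal per replicate and 1000 bootstrap samples of peaks for the correlation.

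The genes named are 10 fixed genes (Dad, brk, dpp, zen, bi, salm, pnr, tup, tin and Mad), those with the TSS nearest to the 10 strongest peaks and, in each list, up to 4 bound members with the strongest peak. One gene that this rule selects is not reported here. The name slp1, and neighbours named as the place of a peak, fall outside that rule and were added after their values were seen.

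Alternatives set before the data were examined were a promoter distance of 250 or 1000 bp, gene spans extended by 1 or 10 kb, the nearest TSS only, a summit within 500 bp of a TSS, the 1000 strongest peaks, motif windows of 50 or 200 bp to each side, Fisher's exact test without matching on length, and circular shifts of the peaks (100 for the promoter share and 1000 for gene lists). Others were pooled-list peaks below the threshold as background, matched on GC content in bins of 5 percentage points for motifs, summits within 100 bp or an overlap of 0.5 of each peak as the match of replicates, the dm3 lists, and the 3590 strongest peaks of each replicate alone. The comparison of the strongest peaks of the replicates' own lists with each other was added after the data were seen.

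The tests were tried on simulated data first. For gene lists of random genes, 2.5% of 200 had p under 0.05, and 94.5% did once unbound members were made bound with a probability of 0.6. Binding was simulated there gene by gene, for genes drawn at random. The rates therefore do not cover lists of neighbouring genes that share a summit. For signal ranks, 3.33% of 60 unchanged lists and 98.3% of 60 lists with halved percentiles passed. At 3590 random positions, 5.63% of 160 motif tests had p under 0.05, and the DREF site planted at 4.99% of summits was recovered at 5.13% over the flanks. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.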

Results

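Mad is the transcription factor (Smad) that is phosphorylated by activated receptors for Dpp, the main bone morphogenetic protein (BMP) of the fly, and then enters the nucleus. Chromatin was precipitated with an antibody against GFP from whole Drosophila melanogaster embryos of both sexes, 0 to 24 h old, that carried a transgene for Mad fused to enhanced GFP. The series held 1 group of 2 biological replicates and no second condition, so the questions it could answer were where the fusion protein gave peaks and how far the replicates agreed. Each replicate had a list of 30000 peaks, both replicates together had a pooled list of 30000, and a further list held the peaks kept by the authors' threshold on reproducibility. All positions are in build dm6. Read depths were not given in the sources used here, so the peak signals are the authors' own values and intervals of shares cover counting error over peaks only.

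The threshold kept 3590 peaks with a median width of 396 bp and a median signal of 106. The strongest, with a signal of 1447, lay on chromosome arm 3L at 19590445 to 19590811, in the promoter region of CG14100, a gene without a given name. Its summit at 19590622 was 98 bp upstream of the transcription start site (TSS), and its signal was 693 in replicate 1 and 757 in replicate 2. The second peak, with a signal of 1239, lay on 2L at 480895 to 481269 in an intron, 1379 bp upstream of the nearest TSS, that of cbt, and in the span of ush extended by 5 kb. ush encodes a zinc-finger cofactor of GATA factors. Of the other 8 of the 10 strongest peaks, 6 lay in promoter regions, those of Ugalt (signal 1205), px (1121), Chro (1094), ph-p (994), Tcs5 (992) and PNPase (933), and the other two lay in introns near CG11050 (1138) and Lk6 (888). Chro encodes a chromodomain protein and ph-p a Polycomb group protein. All 3590 thresholded peaks were the peaks of highest signal in the pooled list. The lowest signal kept was 70.5 and the highest left out was also 70.5.

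The replicates shared most of these peaks. Of the 3590, 2682 (74.7%, 95% Wilson interval 73.3 to 76.1%) overlapped by at least 1 bp a peak among the 3590 of highest signal in each replicate list. These peaks were selected on both replicates at once, since the pooled signal was a median of 1.00 times the sum of the replicate signals, so part of this share comes from the selection. In a comparison added after the data were seen, the 3590 strongest peaks of each replicate's own list were set against each other. Of those of replicate 1, 2699 (75.2%, interval 73.7 to 76.6%) overlapped one of replicate 2, and 2681 (74.7%) did the other way, against 2.01% and 1.95% on average for random placement over the arms. A further 369 peaks were among the highest of replicate 1 alone, 490 among those of replicate 2 alone and 49 among those of neither, and 3585 (99.9%) overlapped a peak of both whole lists. Across those 3585 peaks the signals of the replicates had a Spearman correlation of 0.706 (95% bootstrap interval 0.685 to 0.724) and a Pearson correlation of 0.803 on the log2 scale. Both are across peaks, which are not independent replicates. The peaks were kept by a cut on the pooled signal, so both correlations describe the kept peaks and not the whole lists. The median signal was 50.6 in replicate 1 and 60.6 in replicate 2, with a median log2 ratio of 0.28 (SD 0.46 across peaks), and replicate 2 was higher at 2715 peaks. On chromosome 4 the median log2 ratio was 0.05 over 19 peaks, against 0.26 over 700 on arm 2L and 0.29 over 724 on arm 3L. This difference between arms was not tested.

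**Figure D1:**
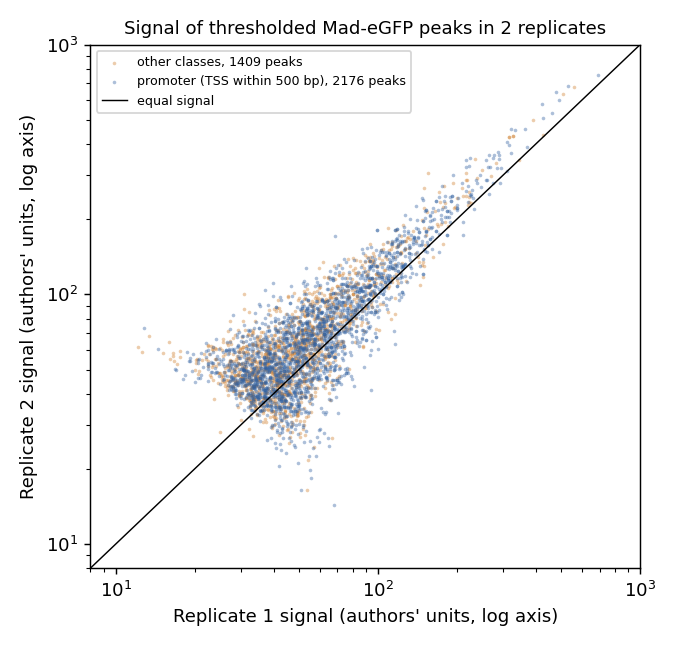
Signal of 3585 thresholded peaks in replicate 1 (x axis) and replicate 2 (y axis), both in the authors' units on log axes, with 1 point per peak, coloured by whether the summit lay within 500 bp of a TSS. Most points lie above the line of equal signal, since replicate 2 was higher at 2715 peaks.

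Mad-eGFP peaks were concentrated at promoters and nearly missing from coding sequence. Of 3590 summits, 2181 (60.8%, interval 59.1 to 62.3%) lay within 500 bp of an annotated TSS, a region that makes up 13.6% of the bases of the main chromosome arms, which is a 4.48-fold excess. Coding exons outside promoters held 9 summits (0.251%, interval 0.132 to 0.476%) against 13.1% of bases, and 3' UTRs held 25 (0.696%) against 5.07%. Introns held 962 summits (26.8% against 39.5% of bases) and intergenic sequence held 359 (10% against 27.1%). At promoters near a protein-coding TSS, the median summit lay 75 bp upstream (quartiles 149 and 22 bp upstream), and 82.2% of 2090 summits were on the upstream side.

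Exact binomial tests against the share of bases, adjusted by the Benjamini-Hochberg method over 7 classes, gave an adjusted p of 3.55e-200 for coding exons, 1.57e-49 for 3' UTRs, 3.51e-57 for introns and 2.99e-142 for intergenic sequence. The promoter share exceeded that of all 100 circular shifts of the peaks along their arms, which averaged 13.6% and reached 15.4% (permutation p = 0.0099, the smallest they can give, one-sided). Against the 25742 peaks of the pooled list that overlapped no thresholded peak, of which 27.1% were at promoters and 17.9% in coding exons, thresholded summits were 2.24-fold more often at promoters. The share in 5' UTRs (0.669% against 0.780% of bases) had an adjusted p of 0.591, but was lower than the 1.21% of the peaks below the threshold (adjusted p = 0.00376, Fisher's exact test). Other exons held 0.836% of summits and 0.821% of bases (adjusted exact p = 0.853).

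**Figure D2:**
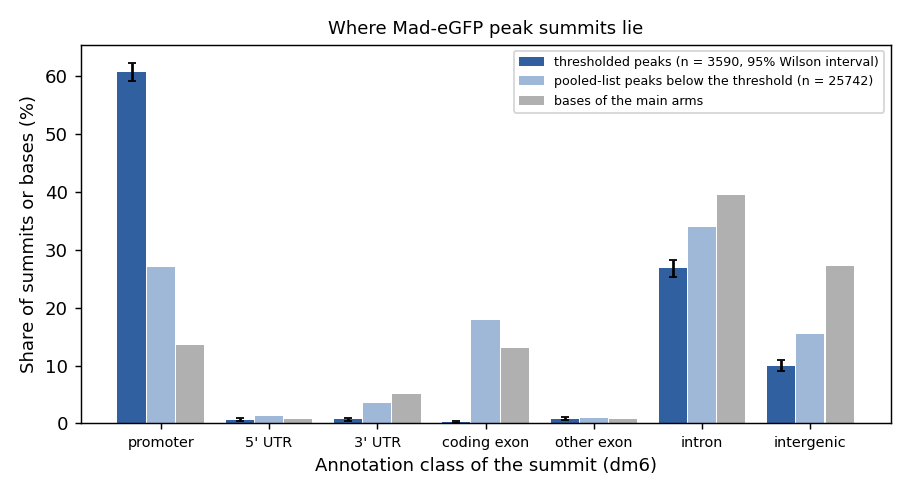
Share of summits (%) in each annotation class for 3590 thresholded peaks with 95% Wilson intervals and for 25742 pooled-list peaks below the threshold, beside the share of bases of the main arms. Promoters held 60.8% of thresholded summits and 13.6% of bases, and coding exons 0.251% and 13.1%.

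Peak density was similar on the 5 large chromosome arms and lower on chromosome 4. It was 29.8 peaks per Mb on arm 2L, 26.6 on 2R, 25.9 on 3L, 26.6 on 3R and 26.5 on the X, and 14.3 on chromosome 4, which held 19 peaks and was not tested. The density on the X was 0.976 times that on arms 2L to 3R together (p = 0.599, two-sided exact binomial test).

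Genes of the BMP pathway and known targets of Dpp held peaks, though not more often than genes of like length at the set threshold. A gene counted as bound when a thresholded summit lay in its span or within 5 kb of it, which held for 6393 of 13945 protein-coding genes, from 25.8% of the shortest 10% of genes to 60.04% of the longest. Of 30 Dpp target genes, 20 were bound where 16.4 were expected from random lists matched on gene length (adjusted permutation p = 0.509). Of 28 BMP pathway components, 21 were bound where 14.9 were expected (permutation p = 0.0278, adjusted permutation p = 0.146 over 21 lists). The p-values are from 100000 random lists and two-sided.

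Mad itself, a gene of arm 2L at 3146056 to 3159643 on the minus strand, held 3 peaks in its span extended by 5 kb. Of these, 1 with a signal of 82.6 lay outside the gene, at the promoter of its neighbour toc. The strongest ranked 71st, at 3153269 to 3153556 in an intron, 642 bp upstream of the nearest Mad TSS, with a signal of 463 (156 in replicate 1 and 307 in replicate 2). Dad, the inhibitory Smad that is induced by the pathway, held 5 peaks, and the strongest was in an intron at 17065000 to 17065395 of arm 3R with a signal of 176, nearest the TSS of Ns1. The single peak at brk, which encodes a repressor of Dpp targets, was 779 bp upstream of its TSS at 7306962 to 7307357 of the X (signal 136). dpp held 1 intronic peak at 2433422 to 2433817 of 2L (signal 142), and bi held 1, at 4446037 to 4446432 of the X (signal 97.48). tin, a homeobox gene of the heart, had a peak 208 bp upstream of its TSS (signal 133). At tup the strongest of 3 peaks, with a signal of 186, lay nearest the TSS of its neighbour CG10602. No thresholded summit lay within 5 kb of zen, salm or pnr.

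Among the Dpp targets the strongest signals were at ush (1239), bam (605), Ance (300) and magu (236). The peak counted for bam was the one 3 bp from the TSS of RpS27, and that for Ance lay at the promoter of Smg5. For 8 of the 20 bound Dpp targets the strongest peak was nearest a TSS of the gene itself. Among BMP components the strongest were gbb, a BMP ligand (471, at the promoter of eIF6), Mad, Med, the common Smad (336, at the promoter of Mnat9), and cv (332, intergenic). The strongest peak was nearest the gene's own TSS in 8 of the 21 bound components. Counted at promoters only, with a summit within 500 bp of a TSS, 7 Dpp targets were bound (7.59 expected, adjusted permutation p = 0.998) and 5 BMP components (6.91 expected, adjusted permutation p = 0.818). When the peaks were shifted along their arms in place of drawing genes of like length, the Dpp targets passed the threshold, at 1.86 times the expected number (adjusted permutation p = 0.0210), as did the BMP components at 2.16 times (adjusted permutation p = 0.0140). Shifting takes peaks off promoters, where 60.8% of summits lay before and 13.6% on average in the shifts run for the promoter share. A list that passes under shifts is therefore not set apart from genes in general. The BMP components also passed by Fisher's exact test without matching on length (adjusted p = 0.0106).

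Ribosomal protein genes were the list most often bound. Of 92, 76 (82.6%) held a peak where 37.0 were expected, a ratio of 2.05, and 67 did within 500 bp of a TSS where 14.3 were expected. Both had an adjusted permutation p of 0.00021, and the p of 2e-05 before adjustment is the smallest that 100000 lists can give. Among the strongest were RpS27 (signal 605, summit 3 bp downstream of its TSS), RpL7 (557) and RpL23A (367). The strongest peaks of the bound ribosomal protein genes also ranked higher than those of other bound genes of like length, at a median of the 20.8th percentile from the top against the 37.9th (adjusted p = 0.0120, permutation test of 10000 lists), and no other list passed that test. Taken from replicate 1 alone, no list passed it.

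Odorant and gustatory receptor genes, which are expressed in chemosensory neurons, were the list most clearly depleted. Of 119, 19 were bound where 52.1 were expected, a ratio of 0.365 (adjusted permutation p = 0.00021), and 0 had a summit within 500 bp of a TSS where 21.6 were expected (adjusted permutation p = 0.00021). For 3 of the 19 the strongest peak was nearest a TSS of the gene itself. Some of the strongest peaks counted lay at other genes, such as that of Or85f (348) at the promoter of RpL34b and that of Gr94a (159) at p53, while those of Gr5a (208) and Gr61a (158) were nearest Tre1 and CG13901. Against circular shifts of the peaks the receptors had a ratio of 0.704 and the call was lost (adjusted permutation p = 0.403). Shifted peaks lose their concentration at promoters, so this ratio is not on the same scale as the length-matched one. The shifts do keep neighbouring genes together, while the length-matched draws treat genes as independent. Neighbouring receptor genes can share a summit or lack one together, so the length-matched p-values may be too small.

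The other 17 lists did not pass the threshold with length-matched draws of all thresholded peaks, though 5 did under an alternative. Components of the Wnt pathway were bound in 18 of 23 (12.96 expected, adjusted permutation p = 0.150). The highest signals were at sgg, the GSK3 kinase (305), fz3 (251), dsh (193) and fz (192). The peaks of fz3, dsh and fz were nearest the TSS of RpL22, CG1737 and CG13482, in that order. For 7 of the 18 the strongest peak was nearest a TSS of the gene itself. Gap and pair-rule genes were bound in 5 of 20 (10.02 expected, adjusted permutation p = 0.150), namely slp2 (348), bcd (140), oc (114), cad (109) and slp1. For 4 of these 5 the strongest peak was nearest a TSS of the gene itself, while that of cad lay at the promoter of Pomp. Neural genes were bound in 5 of 19 (9.77 expected, adjusted permutation p = 0.150). Among them, elav had a signal of 446, and nSyb, insc and pros had 136, 113 and 91.3. The peaks of nSyb, insc and pros lay at the promoters of Bgb, sktl and mgr. For 1 of the 5 neural genes the strongest peak was nearest its own TSS. Of 16 chorion and vitelline membrane genes, which are expressed in ovarian follicle cells, Vm34Ca alone was bound (5.70 expected, adjusted permutation p = 0.0984). Its peak lay at the promoter of CG42784. Of these lists, the Wnt pathway passed under circular shifts (ratio 2.03, adjusted permutation p = 0.0140) and by Fisher's exact test without matching on length (adjusted p = 0.0106). The chorion and vitelline membrane genes passed by Fisher's exact test (adjusted p = 0.0105) and without replicate 1 (adjusted permutation p = 0.0116).

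Bound members numbered 13 of 21 for the Notch pathway (9.89 expected, adjusted permutation p = 0.509), with E(spl)m7-HLH and E(spl)m8-HLH sharing a peak of signal 304 at the promoter of gro, and mam (241) and N (237) next. The peaks of mam and N were nearest the TSS of CG18371 and CG18508. The EGFR pathway had 12 of 16 (9.18 expected, adjusted permutation p = 0.509), led by its ligand spi (330), aos (315), S (278) and aop (265). The Hedgehog pathway had 6 of 15 (8.32 expected, adjusted permutation p = 0.549), led by shf (158, at the promoter of Coq7) and rdx (134). The strongest peak was nearest the gene's own TSS in 4 of 13 bound Notch genes, 8 of 12 EGFR genes and 3 of 6 Hedgehog genes. Lists of embryonic tissues had 10 of 19 for amnioserosa and dorsal ectoderm (10.2 expected, adjusted permutation p = 1), 8 of 20 for dorsal mesoderm and heart (10.7, adjusted permutation p = 0.549), 10 of 20 for trachea (11.5, adjusted permutation p = 0.786) and 11 of 19 for midgut endoderm (10.9, adjusted permutation p = 1). Mef2 led the mesoderm with 719 at the promoter of Pal1, grh the trachea with 233 and fkh the endoderm with 175. Dorsal-ventral patterning genes were bound in 10 of 18 (9.33 expected, adjusted permutation p = 1), Hox genes in 5 of 8 (4.77, adjusted permutation p = 1) and muscle genes in 7 of 16 (8.99, adjusted permutation p = 0.625). Blood and fat body genes were bound in 6 of 15 (8.18, adjusted permutation p = 0.571), epidermis and cuticle genes in 6 of 15 (7.66, adjusted permutation p = 0.714) and germline genes in 8 of 11 (5.70, adjusted permutation p = 0.519). In the 1000 strongest peaks the Notch pathway passed, at 2.75 times the expected number against 1.31 in all peaks (adjusted permutation p = 0.00644). The draws count genes that share a summit, such as E(spl)m7-HLH and E(spl)m8-HLH, as independent, so this p-value may be too small. Under circular shifts the EGFR pathway (ratio 1.94, adjusted permutation p = 0.0252) and the germline genes (2.56, adjusted permutation p = 0.0280) passed. For 1 of the 8 bound germline genes the strongest peak was nearest a TSS of the gene itself.

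**Figure D3:**
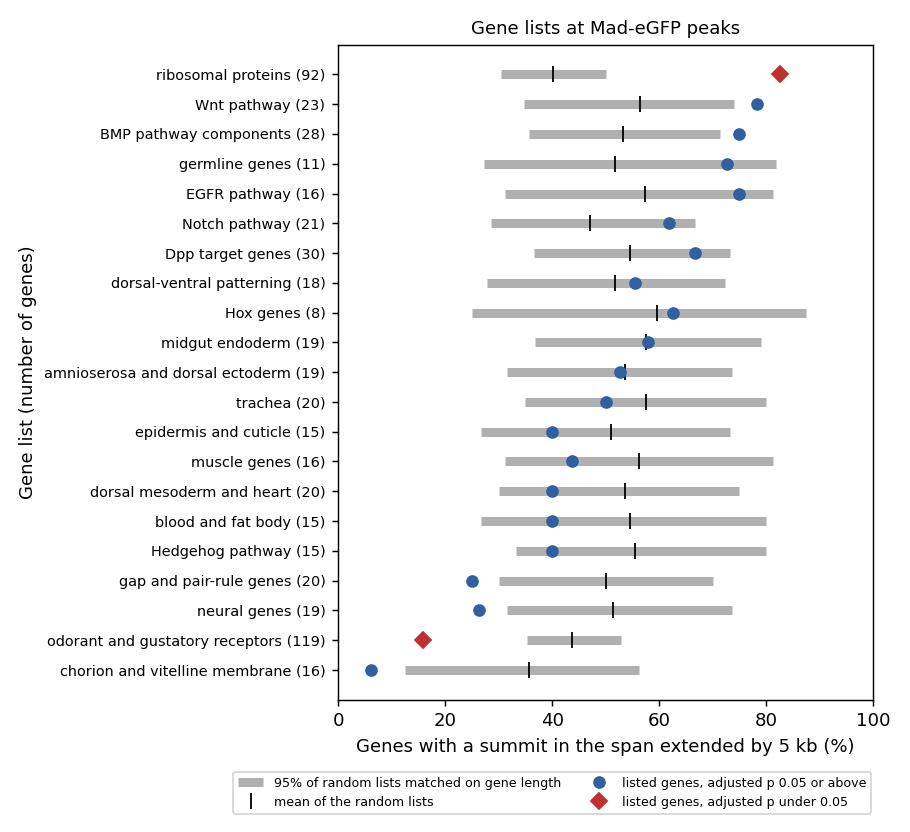
Share of genes (%) with a thresholded summit in their span extended by 5 kb, for 21 lists, with bars for 95% of the random lists matched on gene length. Ribosomal protein genes (82.6% bound) and odorant and gustatory receptor genes (16.0%) lie outside their bars and passed the adjusted threshold, and 5 other lists lie outside their bars without passing it.

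The sequence most enriched at the summits was TATCGATA, the site of DREF, a factor of promoters of broadly expressed genes. It occurred within 100 bp of 221 of 3590 summits (6.16%, interval 5.42 to 6.99%) against 0.446% of flanks of the same width 600 bp away, a 13.8-fold excess (adjusted p = 4.45e-43, exact McNemar test, two-sided, over 16 motifs). GGTCACACT, the site of M1BP, another factor of such promoters, occurred at 113 summits (3.15% against 0.348%, 9.04-fold, adjusted exact p = 1.94e-18). Against peaks below the threshold of the same GC content the excess was 2.70-fold for the DREF site (adjusted exact p = 2.67e-15) and 1.77-fold for the M1BP site (adjusted exact p = 0.00191). That background was not matched on promoters, which held 27.1% of all peaks below the threshold and 60.8% of thresholded summits. Of the 221 summits with the DREF site 213 were at promoters, as were 111 of the 113 with the M1BP site. How much of the excess over the matched background comes from promoters was not measured. Among the 1000 strongest peaks the M1BP site did not pass (adjusted exact p = 0.0989).

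Over all thresholded summits, no site bound by Mad passed the threshold for an excess over the flanks. GGCGCC, the GC-rich palindrome, occurred at 164 summits (4.57%, interval 3.93 to 5.30%) against 3.90% of flanks (adjusted exact p = 0.379), and with 200 bp windows it was 0.33 percentage points lower than in flanks (adjusted exact p = 0.313). In bins of 50 bp it was highest just after the summit, at 1.59% of peaks. It was at 1.45% just before the summit and at 1.48% in the bin from 400 to 450 bp. The bins were not tested. The looser Mad site GCCGNC was less frequent at summits (15.3% against 25.1%, adjusted exact p = 5.59e-25), and so were the Smad box CAGAC (18.1% against 24.0%, adjusted exact p = 1.48e-08) and the Brinker site GGCGYY (18.9% against 21.8%, adjusted exact p = 0.00596). The summits had a lower GC content than their flanks, 37.8% against 43.9% on average. Against peaks below the threshold of the same GC content, GGCGCC was more frequent at summits (4.57% against 3.26%, adjusted exact p = 0.0269), GCCGNC did not differ (adjusted exact p = 0.864) and CAGAC was lower (18.1% against 20.4%, adjusted exact p = 0.0488). That background was not matched on annotation class. Promoters held 27.1% of all peaks below the threshold and 60.8% of thresholded summits, and coding exons held 17.9% and 0.251%. The Brinker site turned in direction there (18.9% against 17.3%, adjusted exact p = 0.211), and also lost its call with 50 bp windows (adjusted exact p = 0.0816) and without replicate 2 (adjusted exact p = 0.102). Of the 14 distinct orders of the same 6 bases, GGCGCC ranked first in its excess of summits over flanks. With 14 orders no rank can pass the threshold, so this is a description and not a test.

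Of the other motifs, the homeodomain core TAATTA was more frequent at summits than in flanks (14.7% against 10.4%, adjusted exact p = 5.03e-07), but less frequent than in peaks of the same GC content (17.05%, adjusted exact p = 0.0324). The site of Zelda, CAGGTAG, was lower than in flanks (0.780% against 1.43%, adjusted exact p = 6.07e-04), as was the CTCF site (3.23% against 5.19%, adjusted exact p = 8.56e-06), and neither differed from peaks of the same GC content (adjusted exact p = 1 and 0.211). The call for Zelda was also lost in the 1000 strongest peaks (adjusted exact p = 0.104) and without replicate 2 (adjusted exact p = 0.0709). Sites of GAGA factor, Twist, Dorsal, GATA factors and Tinman had adjusted p-values of 0.330, 0.710, 0.710, 0.192 and 0.379. GAGA sites passed with other windows, lower than in flanks with 50 bp (adjusted exact p = 8.01e-04) and higher with 200 bp (adjusted exact p = 0.0311). The composite silencer and activating elements of Mad with Medea occurred at 5 and 8 summits. These were 0.139% and 0.223% of summits, against 0.153% and 0.139% of flanks, and neither passed. At such counts only a large difference could have passed.

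**Figure D4:**
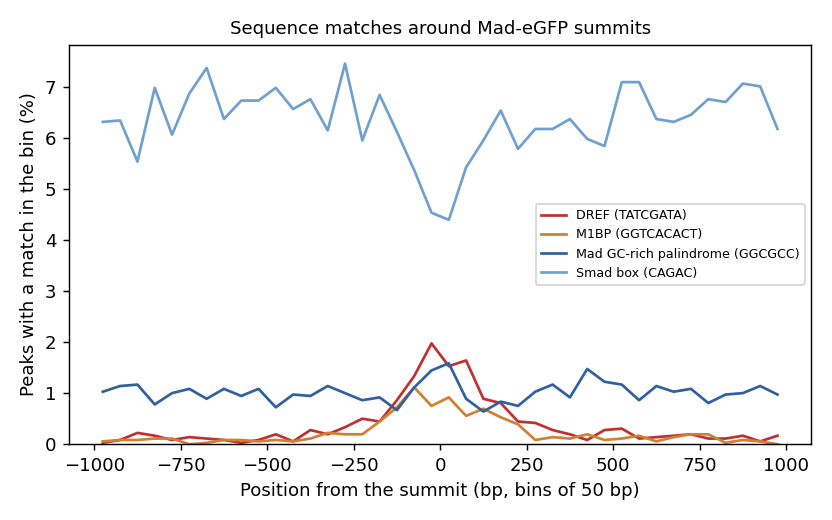
Share of 3590 thresholded peaks (%) with a match of each sequence, in bins of 50 bp from 1000 bp on one side of the summit to 1000 bp on the other. The DREF site reached 1.98% in the bin just before the summit and GGCGCC 1.59% in the bin just after it, while the Smad box fell to 4.40%.

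At single summits, the strongest Mad peak had 1 copy of GGCGCC within 100 bp, and none of the strongest peaks of Dad, brk, dpp, bi, tup or tin had one. The looser site GCCGNC had 1 match each at dpp and tup and 0 at Mad, Dad, brk, bi and tin. The Smad box CAGAC had 0 at all of these peaks. The 41 bp around the Mad summit, at 3153375 to 3153415 of 2L, read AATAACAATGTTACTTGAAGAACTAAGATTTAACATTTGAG. Those around the brk summit, at 7307140 to 7307180 of the X, read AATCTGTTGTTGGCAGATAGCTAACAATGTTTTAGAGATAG. Of the 10 strongest peaks, 0 had GGCGCC, TATCGATA or GGTCACACT within 100 bp of the summit. The strongest, at CG14100, read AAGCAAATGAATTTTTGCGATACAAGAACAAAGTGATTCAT at 19590602 to 19590642 of 3L.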

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

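The result below was chosen for a closer look after it was seen, and no test was run on it. In the dm3 lists, which enter no comparison of genes or sequence, 35 peaks of the pooled list lay on heterochromatin and unplaced scaffolds outside the main arms. The control data were not used here, so there is no level to set this count against. The list of replicate 1 held 47 such peaks and that of replicate 2 held 50. The dm3 thresholded list held 0 of them, and the dm6 lists hold none. No biological explanation was tested.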

How the results depend on the processing

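All alternatives were set before the data were examined, except that the strongest peaks of the replicates' own lists were compared after the data were seen (75.2% and 74.7% shared). Of 358 values under alternatives, 323 stayed on the same side of the threshold, or within their interval or 1.5 times. The promoter share stayed above that of the genome under every alternative, from 52.3% within 250 bp of a TSS to 70.1% within 1000 bp. The causes of the changes below were not tested.

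The share of peaks in both replicates was 100% for the 1000 strongest peaks, 99.9% with whole replicate lists, 68.7% with summits within 100 bp and 66.2% with an overlap of 0.5 of each peak. The Spearman correlation was 0.750 for the 1000 strongest peaks and 0.680 with summits within 100 bp. Lists past the threshold numbered 2 by length-matched draws, 3 with the 1000 strongest peaks (Notch pathway gained) and 3 without replicate 1 (chorion and vitelline membrane genes gained), 5 by Fisher's exact test without matching and 6 by circular shifts, under which the Dpp targets had a ratio of 1.86. Fisher's test leaves the length of genes uncorrected, by construction. Circular shifts leave the concentration of peaks at promoters uncorrected, so passing under them does not single out a list. Without replicate 1 or 2 the number of lists past the rank test was 1 and 0.

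Motifs past the threshold numbered 8 against the flanks and 5 against peaks of the same GC content. With that background, which was not matched on promoters, GGCGCC passed, at 1.31 percentage points over it. The direction turned for the homeodomain core (-2.31 points), the Brinker site (1.53) and the CTCF site (0.669), and with windows of 200 bp for the GAGA site (1.87). It also turned in 8 motif values that passed in neither setting, among them GGCGCC with 200 bp windows (-0.33) and, by GC content, GAGA (2.01) and Tinman (-0.56). In percentage points over the background, calls were lost for GCCGNC by GC content (-0.42), Brinker with 50 bp windows (-1.99), and Zelda (-0.75) and M1BP (1.30) in the 1000 strongest peaks, and GAGA gained one with 50 bp windows (-2.99). Without replicate 1 Brinker (-3.41) and Zelda (-0.46) kept theirs, and without replicate 2 both lost them (-2.44 and -0.32). Zelda also lost its call by GC content (0), as did the receptors by circular shifts. In all, 10 calls were lost and 14 gained, counting those whose direction turned. Read depths were not given, so what depth limits could not be measured.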

Other observations

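Everything below was chosen after the main results were seen. The predictions for active promoters and for divergent gene pairs were written before their test values were seen, and those for base composition, the Mad palindrome and the Mad locus after. Those for the palindrome and the locus were also changed once their values were known. Families picked by symbol held peaks unevenly (10 families, length-matched draws, Benjamini-Hochberg over the families). The draws treat genes as independent, though neighbouring genes can share a summit or lack one together. No test that keeps neighbours together was run on these families, so the p-values may be too small. Mitochondrial ribosomal protein genes had a summit within 500 bp of a TSS in 31 of 73 where 8.75 were expected (3.54-fold, adjusted permutation p = 1e-04). Cuticle protein genes had 0 of 70 (10.6 expected, adjusted permutation p = 1e-04), cytochrome P450 genes 1 of 85 (18.2 expected, adjusted permutation p = 1e-04), ionotropic receptor genes 1 of 60 (12.6 expected, adjusted permutation p = 1e-04), odorant-binding protein genes 1 of 51 (5.98 expected, adjusted permutation p = 0.0403) and Osiris genes 0 of 25 (4.82 expected, adjusted permutation p = 0.0194). Proteasome subunits (9 of 48, 7.91 expected, adjusted permutation p = 0.788), complex I subunits (10 of 40, 6.08 expected, adjusted permutation p = 0.155), initiation factors (14 of 44, 9.09 expected, adjusted permutation p = 0.135) and tRNA synthetases (8 of 17, 3.98 expected, adjusted permutation p = 0.0796) did not pass. Within spans extended by 5 kb the odorant-binding protein genes did not pass either (13 of 51, 17.5 expected, adjusted permutation p = 0.285), while the other 5 calls held. By biotype, a summit lay within 500 bp of a TSS of 19.7% of 13945 protein-coding genes, 5.21% of 3261 non-coding RNA genes, 3.10% of 290 tRNA genes and 25% of 32 snRNA genes (interval 13.3 to 42.1%).

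Among 25418 k-mers of 8 bases, 1157 were more frequent at summits than in the right flank after adjustment and 1287 less frequent. By p-value TATCGATA ranked first (adjusted exact p = 7.07e-40) and overlapping forms such as ATCGATAG followed. The third was CAACACTG, at 4.60% of summits against 0.627% of flanks (7.33-fold, adjusted exact p = 1.72e-24), which no listed motif covers, and CACAGTGG stood at 4.60% against 1.03% (adjusted exact p = 3.68e-19). Among the less frequent ones, GCTCCTCC had the lowest p-value, at 0.223% against 1.88% (adjusted exact p = 4.50e-13). Of 23 k-mers with GGCGCC, 3 were more frequent at summits.

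Thresholded summits carried the DREF and M1BP sites far more often than their flanks, while GGCGCC did not pass against the flanks. Base composition, taken as GC content, does not account for all of the DREF sites, which were 2.70-fold more frequent than in peaks of the same GC content. The excess over the flanks was larger, at 13.8-fold, since the flanks held the site at 0.446% and those peaks at 2.28%. How much of this drop comes from GC content was not measured. The background of peaks of the same GC content was not matched on promoters, which held 27.1% of all peaks below the threshold and 60.8% of thresholded summits. Part of the 2.70-fold excess may therefore come from promoters. Mad bound to its palindrome does not account for most peaks, because 4.57% of summits had GGCGCC within 100 bp. The prediction first written was on the strongest against the weakest 359 peaks, and it was replaced by one on the share over all summits. That first comparison showed no clear difference, at 2.79% and 4.46% (-1.67 points, 95% interval -4.40 to 1.06, Fisher's exact p = 0.318), and the 359 peaks next in strength had 5.85%. A signal that every active promoter gives is a candidate explanation, since outside promoters the DREF site was at 8 of 1409 summits (0.568%) against 0.390% of flanks (1.45-fold, exact McNemar p = 1), while at promoters it was at 9.77% against 0.481%. GGCGCC showed no excess at promoters, at 4.72% against 4.65% of flanks (1.01-fold, exact McNemar p = 0.887). Outside promoters it was at 4.33% against 2.73% (1.58-fold, exact McNemar p = 0.0265, not adjusted), which such a signal would not by itself bring. The same values would follow if the fusion protein itself sat at these promoters, and no control precipitation was analysed here to separate the alternatives.

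Mad itself held a peak that ranked 71st, and extra copies of the locus in the transgene could raise the number of peaks there. The pooled list had 0.560 peaks per kb in the Mad span extended by 20 kb, where the median gene of arm 2L had 0.314, which put Mad at the 91.0th percentile of 2657 genes. The bound first written took any place below the top 2.5% of genes as evidence against extra copies, which this value would have met. It was lowered to the median after the value was seen, because the extent of the transgene and the rise that extra copies would give were not known. On the lowered bound, extra copies and binding in the locus cannot be told apart.

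Thresholded promoter peaks may favour promoters of divergent gene pairs. Of 2090 promoter summits near a protein-coding TSS, 760 (36.4%, interval 34.3 to 38.4%) had as nearest a TSS with another on the opposite strand within 500 bp upstream, against 1176 of 6243 promoter peaks below the threshold (18.8%), a 1.93-fold excess (p = 8.08e-57, Fisher's exact test). No biological explanation of it was tested.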
